A study of Homo sapiens with 12 samples.

How the data were processed

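Expression was measured on Illumina BeadChips in K562 cells, with 3 arrays in each of 4 groups (0.2% DMSO for 24 h and 100 nM dasatinib for 4 h, 8 h or 24 h) and 12 arrays in all. Per the labels, cells were grown with 10% fetal bovine serum and treated in medium with 0.1%. Total RNA was purified on columns with a DNase step, and biotinylated cRNA was made with a TotalPrep kit. The deposited probe signals are in units of intensity, as mean signals per probe that were not background-subtracted and not normalized between arrays. Per the file headers, each signal is followed by a detection p-value for that probe and array, set against negative-control probes. The authors also deposited a value table, whose values are on a log2-like scale. Its 12 columns have the same median, 7.84, and their sorted values differ by at most 0.00061, which is the mark of quantile normalization. The method behind that table is not given in the sources used here, so it served as an alternative alone. The signal columns carry a letter A, B or C within each group. Each of the 12 had a rank correlation of 1 with 1 column of the authors' table, in its own group, and the letters matched replicates 1, 2 and 3. The abbreviation BMS in the signal columns was read as dasatinib, the drug that the labels name.

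The signals were background-corrected, offset and quantile-normalized with the neqc method of limma 3.58.1 in R 4.3.3, with negative-control moments inferred from the detection p-values and an offset of 16, and were taken to log2. Background correction widens the fold changes of dim probes and the offset narrows them, so fold sizes of dim genes depend on both. Of 47314 probes, 30108 named 1 gene, 8 named several and 17198 named none. A probe passed the filter when its detection p was under 0.05 on all 3 arrays of at least 1 group. The 17625 passing probes included 13397 that named 1 gene. For the 2604 genes with more than 1 passing probe, the probe with the highest mean over the 12 arrays represented the gene. This left 10208 genes. The 4228 passing probes without a single gene name were tested apart.

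A linear model with 1 mean per group was fitted to all 12 arrays with limma (8 residual degrees of freedom and 4.08 prior degrees of freedom), and 6 comparisons were made, 3 against DMSO and 3 between times. Moderated two-sided p-values were adjusted over genes by the Benjamini-Hochberg method. A gene was called at an adjusted p under 0.05, and at 2-fold when its absolute log2 fold change was also at least 1. Standard errors (SE) are those of the moderated fit, over 3 arrays against 3. The number of arrays limits the precision of each value. A gene that was undetected on all 3 arrays of 1 of the groups compared is given as a bound, with its values there raised to the lowest normalized value of any detected probe on the same array where they lay below it.

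In all, 22 gene lists were fixed before the data were examined. They cover ERK pathway output, immediate early genes, STAT5 targets, MYC and ribosome biogenesis, FOXO targets with genes of cell cycle exit, erythroid genes, megakaryocyte genes, granulocyte and monocyte markers, lymphoid markers, fibroblast and epithelial markers, DNA replication and E2F targets, mitosis, the BCL2 family, dasatinib target kinases with BCR, cytokine receptors with JAK and STAT5 genes, glycolysis and glucose uptake, the amino acid and ATF4 response, cholesterol synthesis, heat shock and chaperones, lysosome and autophagy, interferon-stimulated genes and reference genes. Each list with enough measured members was tested against the other genes with camera in limma at a preset correlation of 0.01, and p-values were adjusted over all lists and comparisons. The lymphoid list had 2 measured members and was not tested. Some lists share members, such as SPRED1 (ERK and STAT5), ATF3 (immediate early and amino acid) and EPOR (erythroid and cytokine receptors). Their results are therefore not independent. The correlation estimated per list and fry, a rotation test of whether a list's genes move on balance in 1 direction, were alternatives (statmod 1.5.0 was loaded with limma).

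The genes named in the text were chosen by a rule that was also fixed before the data were examined. Against DMSO these were the 8 largest rises and the 8 largest falls among called genes whose arrays did not overlap between groups, and between times 5 and 5. From each list described, the 4 called members with the largest absolute change were taken. A further 17 genes were fixed by name. Not every gene that the rule takes is described in the text. Genes and probes named in the closing section, and list members named because they moved against their list, were chosen after their values were seen.

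The model fit and the list test were run on simulated log2 values with known changes, over 10208 genes drawn independently of each other. Background correction, normalization, the detection filter and the choice of probe were not part of this simulation. In the simulated comparison of 24 h with DMSO the fit recovered 28 of 50 genes changed 1.5-fold and 43 of 50 changed 2-fold. At both 4-fold and 8-fold it recovered 50 of 50. It called 7 of 10008 unchanged genes, among 178 calls. For 24 h against 4 h and against 8 h it called 8 and 11 of them, each among 181 calls. Of 20 lists of 20 genes shifted by 0.5, 20 passed, and of 20 unshifted lists 0 passed. These were random lists of independent genes, so they do not measure the effect of correlation within a real list. Alternatives covered the background correction, the offset, the normalization, the authors' table, the filter, the choice of probe, the groups in the fit, the prior, array weights, a replicate block and leaving out each array.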

Results

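Transcript levels were measured in K562 cells, a human chronic myeloid leukaemia line that carries the BCR-ABL1 fusion kinase, after exposure to dasatinib, an inhibitor of ABL and SRC family kinases. Cells in medium with 0.1% serum received 100 nM dasatinib for 4 h, 8 h or 24 h, or 0.2% DMSO for 24 h, with 3 arrays per group. The comparisons address which genes differ from the 24 h vehicle early in dasatinib exposure and which differ late. The median signal per array was 134 to 160, and each array detected 17175 to 18927 of 47314 probes. Arrays of the same group correlated at a Pearson r of 0.989 to 0.992 across the 10208 genes tested, which are not independent replicates. The highest r to an array of another group was 0.968 to 0.985. The labels do not say whether the arrays of a group came from separate cultures, so the p-values measure only the spread between these samples. Unless stated otherwise, changes are log2 fold changes with the SE of the limma fit, over 3 arrays against 3, and "adjusted p" is the Benjamini-Hochberg value over 10208 genes, or over all lists and comparisons for a list.

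The first principal component held 58.6% of the variance and ordered the groups by length of dasatinib exposure, with DMSO lowest. DMSO arrays lay at -33.6 to -31.4, those at 4 h at -17.9 to -14.9, those at 8 h at 0.574 to 4.87 and those at 24 h at 44.8 to 45.7. Of 10208 genes, 5919 (58.0%) differed among the 4 groups by the moderated F test. The groups did not overlap for 27.7% of genes at 4 h, 46.0% at 8 h and 60.9% at 24 h against DMSO, where chance gives 10%.

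**Figure D1:**
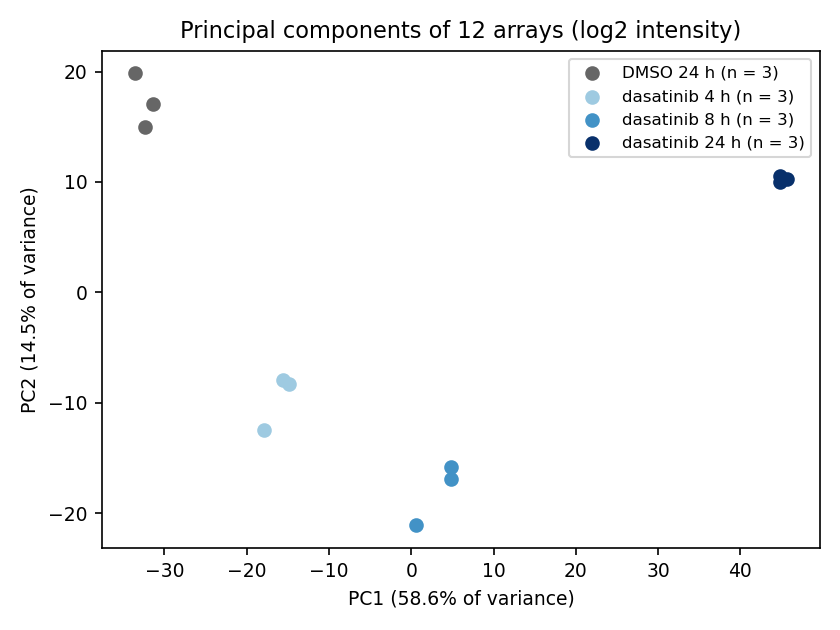
Scores of the 12 arrays on the first and second principal components of normalized log2 intensity, with 3 arrays per group in 4 groups. The first component, 58.6% of the variance, runs from DMSO through 4 h and 8 h to 24 h of dasatinib, and the second holds 14.5%.

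After 4 h of dasatinib, genes of the ERK, STAT5 and immediate early lists were lower and amino acid response genes higher. EGR1, an immediate early transcription factor, fell by 3.89 on the log2 scale (SE 0.19, adjusted p = 1.4e-07), which is 14.8-fold lower. CD69, a surface activation antigen, was at least 7.27-fold lower, and its other probe fell by 1.18. ID1, an inhibitor of basic helix-loop-helix factors, fell by 3.43 (SE 0.13), SLC2A3, a glucose transporter, fell by 2.96 (SE 0.11), and ENC1, an actin-binding protein, fell by 2.64 (SE 0.11). Among rises, MT1X, a metallothionein that binds zinc and other metals, reached 3.58 (SE 0.28, adjusted p = 7.4e-06) and SLC30A1, a zinc exporter, 1.82 (SE 0.14). CDKN1C, a cyclin-dependent kinase inhibitor, rose by 2.78 (SE 0.22), TUBB1, the platelet beta tubulin, by 1.98 (SE 0.21) and ULBP1, a ligand of an activating receptor of natural killer cells, by 1.88 (SE 0.15). FZD2, a Wnt receptor, was at least 3.83-fold higher and EFNA1, an ephrin ligand, at least 2.83-fold higher.

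In total 1219 genes (11.9%) were called at 4 h, 540 higher and 679 lower, and 206 at 2-fold, 71 higher and 135 lower. The vehicle was harvested only at 24 h, so at 4 h and 8 h the drug and the time in low-serum medium differ together. Without DMSO array C 808 genes were called at 4 h, and without background correction 39 genes passed at 2-fold, where the authors' value table gave 22.

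Of 14 measured genes of ERK pathway output, 11 fell and 1 rose at 4 h (11 and 1 adjusted over the list alone), with a median of -1.59 (-1.51 with bounded members at their bound; adjusted p = 7.5e-14). SPRED1, an inhibitor of RAF activation, fell by 2.41 (SE 0.21). SPRY4, a feedback inhibitor of receptor signalling, was at least 3.49-fold lower, CCND1, the D-type cyclin, at least 2.82-fold lower, and SPRY2 fell by 1.53 (SE 0.18). PHLDA1 fell by 2.91 (SE 0.16), while its other probe gave -0.07. KCNN4, a potassium channel, was the member that rose, by 0.40. DUSP6, an ERK phosphatase, gave -0.23 (SE 0.20, adjusted p = 0.54). Of 9 STAT5 targets, 8 fell (9 adjusted over the list alone) and 0 rose, with a median of -1.82 (-1.33 with bounds; adjusted p = 1.6e-16). They included the kinase PIM1, which fell by 2.54 (SE 0.14), SOCS2, a suppressor of cytokine signalling, which fell by 1.33 (SE 0.12), and CISH of the same family, which was at least 3.91-fold lower. CCND2 gave -0.51 (SE 0.16, adjusted p = 0.055). Of 10 immediate early genes, 7 fell and 1 rose (7 and 1 adjusted over the list alone), with a median of -0.59 (-0.48 with bounds; adjusted p = 0.00044). Besides EGR1, IER2 fell by 1.08 and the RNA-binding protein ZFP36 fell by 0.69, and ATF3, a stress-induced factor, rose by 1.07.

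Genes of the amino acid and ATF4 response rose together at 4 h. Of 26 measured, 18 rose and 0 fell (19 and 1 adjusted over the list alone), with a median of 0.59 (adjusted p = 2.7e-14). SESN2, a stress-induced sestrin, rose by 2.03 (SE 0.24), CTH, an enzyme of cysteine synthesis, by 1.33, the factor CEBPB by 1.31 and DDIT4, an mTORC1 inhibitor, by 1.21. Of 26 genes of MYC and ribosome biogenesis, 6 fell and 0 rose (6 and 0 adjusted over the list alone), with a median of -0.25 (adjusted p = 1.9e-05). MYC itself fell by 1.78 (SE 0.13), URB2 fell by 1.14 and RRS1 fell by 0.77. Of 24 genes of the FOXO target and cell cycle exit list, 10 rose and 5 fell (12 and 5 adjusted over the list alone), with a median of 0.29 (adjusted p = 0.0020; adjusted p = 0.082 with an estimated correlation). KLHL24 rose by 1.68, CITED2 by 1.31 and CDKN1B, a cyclin-dependent kinase inhibitor, by 0.57 (SE 0.12), and GADD45A fell by 1.07.

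Of 36 erythroid genes, 8 rose and 1 fell at 4 h (15 and 2 adjusted over the list alone), with a median of 0.24 (adjusted p = 0.0031; adjusted p = 0.17 with an estimated correlation). The erythropoietin receptor EPOR rose by 1.07 (SE 0.12), the delta globin HBD by 0.91, and the factor NFE2 fell by 0.86. Of 21 heat shock genes and chaperones, 7 fell and 0 rose (9 and 0 adjusted over the list alone), with a median of -0.13 (adjusted p = 0.0021; adjusted p = 0.14 with an estimated correlation). The chaperones HSPA1B and HSPA1A changed by -0.93 and -0.78. Of 24 lysosome and autophagy genes, 5 rose and 0 fell (5 and 1 adjusted over the list alone), with a median of 0.15 (adjusted p = 0.024; adjusted p = 0.17 with an estimated correlation). The autophagy kinase ULK1 rose by 1.10. This list did not pass without DMSO array A (adjusted p = 0.064). Of 20 genes of the cytokine receptor list, which also holds JAK1, JAK2, STAT5A and STAT5B, 5 fell and 1 rose (6 and 1 adjusted over the list alone), with a median of -0.26 (adjusted p = 0.014; adjusted p = 0.065 with an estimated correlation). The activin receptor ACVR1B fell by 1.45, TNFRSF1A fell by 1.21 and IL6ST fell by 1.01.

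After 8 h, genes of the ERK and STAT5 lists were lower than in DMSO, most genes of ribosome biogenesis were lower and most erythroid genes higher. ETV5, an ETS factor induced by ERK signalling, was at least 10.9-fold lower, and its other probe fell by 1.08. EGR1 fell by 3.63 (SE 0.19), SLC2A3 fell by 3.51, CD69 was at least 7.56-fold lower, and INPP1, an inositol phosphatase, fell by 2.94. ANKRD55 was at least 5.90-fold lower and MYEOV at least 5.42-fold lower. TUBB1 rose by 3.82 (SE 0.21), CDKN1C by 3.80 (SE 0.22), MT1X by 3.22 (SE 0.28), the GATA factor GATA5 by 3.21, the zinc finger gene ZNF467 by 2.79 and MYBPHL by 2.64. The glutaredoxin GLRX was at least 4.90-fold higher and EFNA1 at least 5.26-fold higher.

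In total 3265 genes (32.0%) were called at 8 h, 1694 higher and 1571 lower, and 529 at 2-fold, 247 higher and 282 lower. Without background correction 129 genes passed at 2-fold, and the authors' value table gave 63.

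Of the 14 ERK genes, 11 fell and 1 rose at 8 h (11 and 1 adjusted over the list alone), with a median of -1.69 (-1.56 with bounds; adjusted p = 1.8e-09). SPRED1 fell by 2.92 and SPRY4 was at least 3.63-fold lower. All 9 STAT5 targets fell (9 adjusted over the list alone), with a median of -1.99 (adjusted p = 4.4e-12). Here PIM1 fell by 2.30, CISH was at least 4.07-fold lower, ID1 fell by 2.61 and CCND2 fell by 1.99 (SE 0.16). Of the 10 immediate early genes, 8 fell and 1 rose (8 and 1 adjusted over the list alone), with a median of -0.62 (-0.55 with bounds; adjusted p = 0.0016). JUNB, an AP-1 subunit, fell by 0.77 and IER2 fell by 0.71. Of the 26 genes of MYC and ribosome biogenesis, 22 fell and 0 rose (23 and 0 adjusted over the list alone), with a median of -0.95 (adjusted p = 1.2e-14). MYBBP1A fell by 1.71, the nucleolar protein NOP16 fell by 1.52, RRP9 fell by 1.49, and MYC fell by 1.37 (SE 0.13).

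Of the 36 erythroid genes, 24 rose and 1 fell at 8 h (24 and 3 adjusted over the list alone), with a median of 0.65 (adjusted p = 7.7e-09). ALAS2, the first enzyme of erythroid haem synthesis, rose by 1.84 (SE 0.28), the carbonic anhydrase CA1 by 1.77, the haem synthesis enzyme ALAD by 1.75, the zeta globin HBZ by 1.63 and EPOR by 1.61. The transferrin receptor TFRC was the member that fell (-0.27). Of the 24 genes of the FOXO target and cell cycle exit list, 14 rose and 4 fell (14 and 5 adjusted over the list alone). Their median was 0.58 (adjusted p = 0.00044, or 0.055 with an estimated correlation). CCNG2, an atypical cyclin, was at least 2.33-fold higher, and CDKN1B rose by 0.68. Of the 26 amino acid and ATF4 genes, 8 rose and 9 fell (9 and 9 adjusted over the list alone; adjusted p = 0.89), with a median of 0.04 and a mean of -0.02, which differ in sign. STC2 fell by 1.84 and the amino acid transporter SLC7A5 fell by 1.06, while CTH rose by 1.11 and the serine synthesis enzyme PSAT1 by 1.04.

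Of the 29 mitosis genes, 13 rose and 0 fell at 8 h (14 and 0 adjusted over the list alone), with a median of 0.24 (adjusted p = 0.00058; adjusted p = 0.18 with an estimated correlation). The phosphatase CDC25C rose by 0.84 and the spindle protein NUSAP1 by 0.73. At 4 h that list did not pass (adjusted p = 0.054), but it did without background correction (0.031), without the detection filter (0.029), with the authors' value table (0.018), with a replicate block (0.042) and without array C of the 4 h group (0.015). Of the 21 heat shock genes and chaperones, 9 fell and 1 rose (9 and 1 adjusted over the list alone), with a median of -0.23 (adjusted p = 0.0021; adjusted p = 0.14 with an estimated correlation). HSPA5, the main chaperone of the endoplasmic reticulum, fell by 1.08. Of the 24 lysosome and autophagy genes, 9 rose and 0 fell (9 and 0 adjusted over the list alone), with a median of 0.25 (adjusted p = 0.0042; adjusted p = 0.11 with an estimated correlation). ULK1 rose by 1.35 and the autophagy receptor SQSTM1 by 0.84. BCL2L11, a pro-apoptotic member of the BCL2 family, was called higher at 8 h at 0.40 (SE 0.12, adjusted p = 0.022), but the mean of all its probes did not pass (adjusted p = 0.50), and the call was lost without DMSO array A (0.063) or C (0.065) and without array A of the 8 h group (0.080). At 4 h it gave 0.22 and at 24 h 0.03.

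After 24 h, the erythroid list had the highest median of the lists tested, 1.46. CA1 was 65.8-fold higher (6.04, SE 0.29, adjusted p = 1.3e-08). SLC4A1, the band 3 anion exchanger of the red cell membrane, was at least 27.6-fold higher, and EPB42, a membrane skeleton protein of red cells, at least 23.7-fold higher. ALAS2 rose by 4.89 (SE 0.28), and TUBB1 was 31.9-fold higher (SE 0.21). ESPN, an actin-bundling protein, was at least 34.5-fold higher, ANO1, a chloride channel, rose from below detection (adjusted p = 4.7e-10), and FAXDC2, a fatty acid hydroxylase family member, rose by 4.76, with 2.51 at its other probe. SLC2A3 fell by 4.71 (SE 0.11, adjusted p = 6.4e-11), EGR1 fell by 3.60 and VGF, a secreted neuropeptide precursor, fell by 3.45 (SE 0.23). The mitochondrial carrier SLC25A22 fell by 3.38, while ETV5 was at least 11.1-fold lower, INPP1 at least 9.88-fold lower and ANKRD55 at least 6.02-fold lower.

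In total 5511 genes (54.0%) were called at 24 h, the duration that the drug and vehicle groups share. Of these, 2746 were higher and 2765 lower, and 1489 passed at 2-fold, 785 higher and 704 lower. Without background correction 613 passed at 2-fold, the authors' value table gave 381, and 2268 probes passed when each probe was counted on its own.

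**Figure D2:**
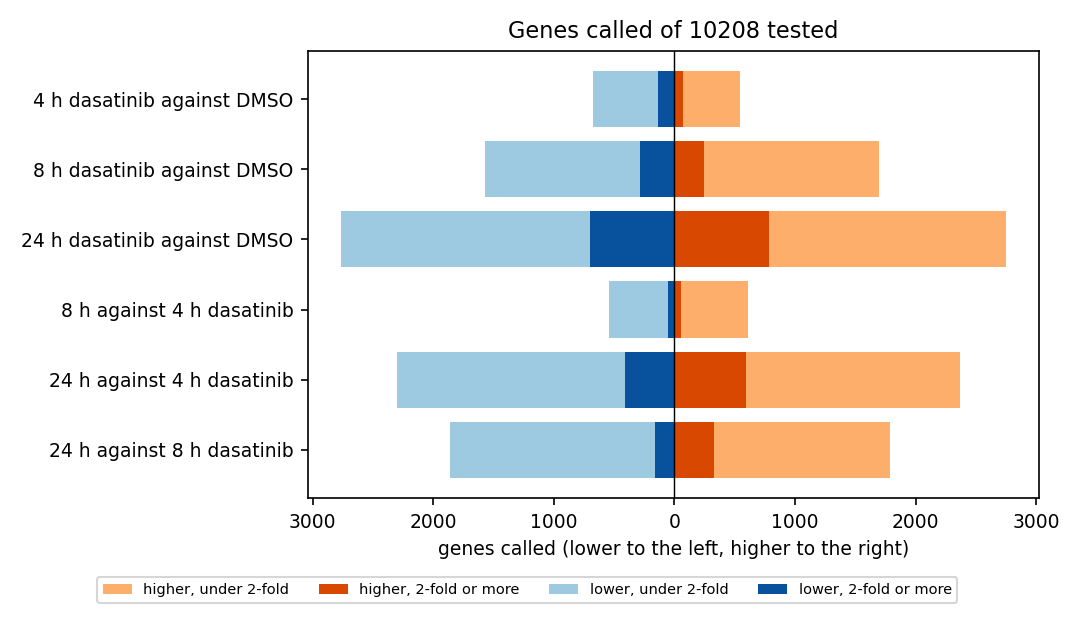
Number of genes called lower (bars to the left) and higher (bars to the right) in each of the 6 comparisons, of 10208 tested, with the darker part of each bar for genes changed 2-fold or more. The count against DMSO was 1219 at 4 h, 3265 at 8 h and 5511 at 24 h.

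Of the 36 erythroid genes, 28 rose and 0 fell at 24 h (29 and 0 adjusted over the list alone), with a median of 1.46 (adjusted p = 3.8e-13). EPOR rose by 2.36 (SE 0.12), whereas the gamma globin HBG1 gave 0.02 (SE 0.09, adjusted p = 0.87). All 26 genes of MYC and ribosome biogenesis fell (26 adjusted over the list alone), with a median of -1.52 (adjusted p = 6.5e-14). RRP12, an export factor of ribosomal subunits, fell by 2.44, RRP9 fell by 2.31, NOP16 fell by 2.15, MYBBP1A fell by 2.13 and MYC fell by 1.04 (SE 0.13). Of the 24 genes of the FOXO target and cell cycle exit list, 17 rose and 4 fell (20 and 4 adjusted over the list alone). Their median was 0.94 (adjusted p = 1.3e-05). CDKN1C rose by 3.87, YPEL3, a growth-arrest gene, by 3.24, YPEL5 by 2.73, PIK3IP1, a PI3K inhibitor, by 2.14 and CDKN1B by 0.84. The 4 that fell were CDKN1A, CDKN2D, KLF2 and KLF6, of which CDKN1A, a cell cycle inhibitor, changed by -1.27.

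Of the 14 ERK genes, 11 fell and 1 rose at 24 h (11 and 1 adjusted over the list alone), with a median of -2.06 (-1.79 with bounds; adjusted p = 1.0e-05). SPRED1 fell by 3.30, PHLDA1 fell by 3.12, SPRY4 was at least 3.70-fold lower, and SPRY2 fell by 1.46. All 9 STAT5 targets fell (9 adjusted over the list alone), with a median of -2.21 (-2.13 with bounds; adjusted p = 2.7e-07). ID1 fell by 3.07, the kinase PIM2 fell by 2.26, SOCS2 fell by 2.21, CCND2 fell by 2.13, PIM1 fell by 1.73 and CISH was at least 4.15-fold lower. The immediate early list did not pass at 24 h. Of its 10 genes 5 fell and 2 rose (5 and 2 adjusted over the list alone), with a median of -0.30 (adjusted p = 0.40). DUSP1, a phosphatase of MAP kinases, rose by 1.28 and KLF10 by 0.86, and IER2 fell by 0.90.

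Of the 21 heat shock genes and chaperones, 18 fell and 0 rose at 24 h (19 and 0 adjusted over the list alone), with a median of -0.69 (adjusted p = 1.3e-06). HSPA4L fell by 1.67 and HSPA5 fell by 1.60. Of 21 genes of glycolysis and glucose uptake, 15 fell and 2 rose (15 and 2 adjusted over the list alone), with a median of -0.48 (adjusted p = 0.00096; adjusted p = 0.11 with an estimated correlation). The pyruvate kinase PKM fell by 2.59 and the hexokinase HK2 fell by 2.14, while the transporter SLC2A1 rose by 1.57. At 4 h and 8 h that list did not pass, with 3 and 5 members lower and adjusted p of 0.10 and 0.18, although at 4 h it passed without background correction (0.047) and without the detection filter (0.034). Of the 24 lysosome and autophagy genes, 11 rose and 3 fell at 24 h (11 and 3 adjusted over the list alone), with a median of 0.35 (adjusted p = 0.014; adjusted p = 0.15 with an estimated correlation). The protease cathepsin B, CTSB, rose by 1.85, ULK1 by 1.59, the peptidase TPP1 by 1.47 and PSAP by 1.17. Of the 29 mitosis genes, 12 rose and 2 fell (12 and 2 adjusted over the list alone), with a median of 0.21 (adjusted p = 0.037; adjusted p = 0.35 with an estimated correlation). NUSAP1 rose by 1.11, the kinesin CENPE by 0.90 and TOP2A by 0.75, and the kinase PLK1 was a member that fell, at -0.48, as was CKS2, at -0.38. That call was lost without array A or B of the 24 h group (adjusted p = 0.069 and 0.051) and under cyclic loess (0.066).

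The lists also held markers of other cell types. Of 2 measured lymphoid markers, CD3D, a T cell receptor chain, gave -0.01 at 4 h and changed by -0.70 at 8 h and -3.35 at 24 h (SE 0.12, adjusted p = 1.2e-09). The other, PTPRC, was not called at any time and gave -0.54 at 24 h (SE 0.27, adjusted p = 0.12). Of 8 fibroblast and epithelial markers, 6 fell and 0 rose at 24 h (6 and 0 adjusted over the list alone), with a median of -0.71 (adjusted p = 0.031; adjusted p = 0.29 with an estimated correlation), and this call was lost without the detection filter (adjusted p = 0.066). The collagen gene COL1A2 fell by 2.30 and the keratins KRT18 and KRT8 changed by -1.06 and -0.92. At 4 h and 8 h that list gave adjusted p of 0.67 and 0.89, and at 8 h its median, 0.01, and its mean differed in sign. Of 4 granulocyte and monocyte markers, 0 were called at 4 h and 8 h and 2 fell at 24 h (adjusted p = 0.73, 0.48 and 0.37). These were lysozyme, LYZ, which fell by 1.57, and SPI1, which fell by 0.93, a call that was lost without DMSO array A (adjusted p = 0.051) and without array A (0.050) or C (0.076) of the 24 h group.

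**Figure D3:**
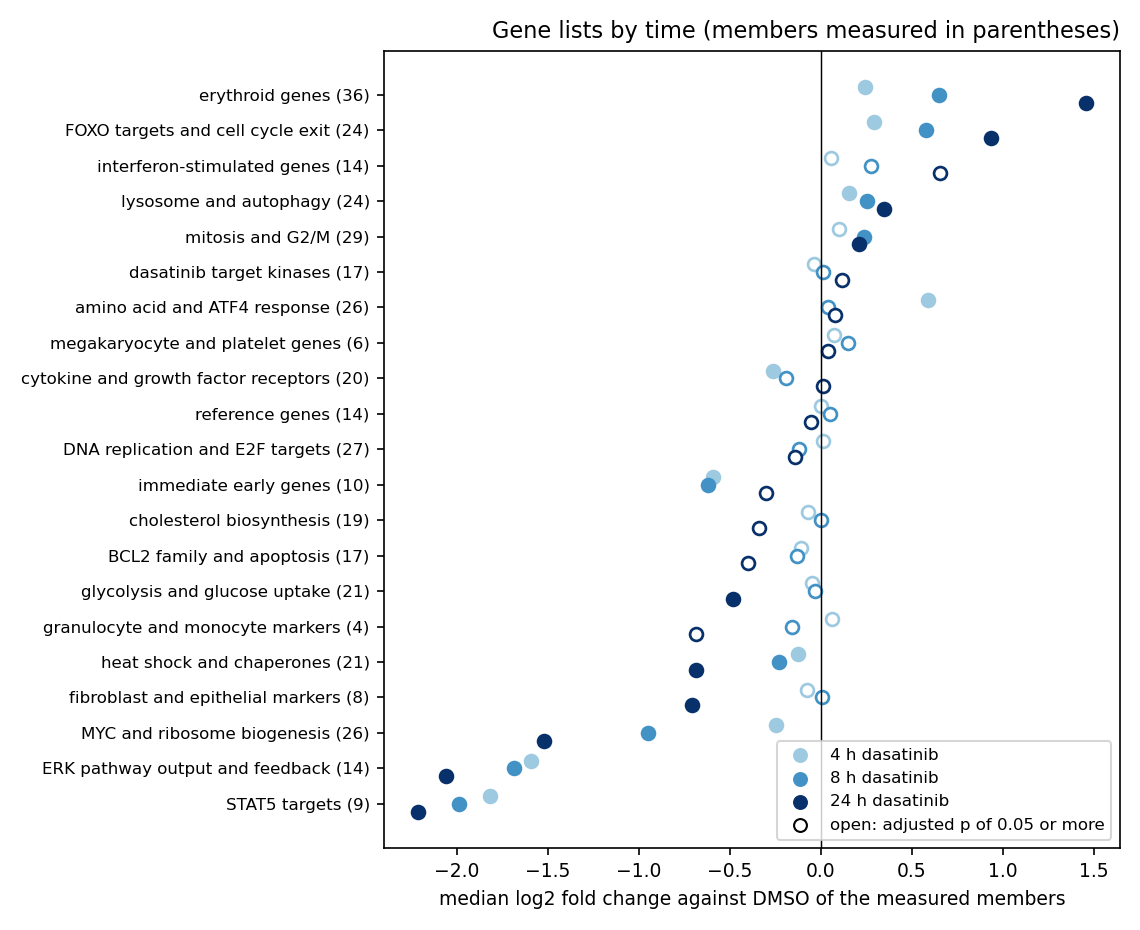
Median log2 fold change against DMSO of the 21 gene lists tested, at 4 h, 8 h and 24 h, with the number of measured members in parentheses. Filled points passed the test of the list and open points did not; the erythroid median reaches 1.46 and that of STAT5 targets -2.21 at 24 h.

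Several lists did not pass at 24 h against DMSO. Of 27 DNA replication genes, 2 rose and 8 fell at 24 h (1 and 6 adjusted over the list alone; adjusted p = 0.25), with the cyclin CCNE1 at -0.77. At 4 h and 8 h that list gave adjusted p of 0.71 and 0.24. Of 17 BCL2 family and apoptosis genes, 2 rose and 8 fell at 24 h (2 and 8 adjusted over the list alone; median -0.40, adjusted p = 0.11). The death receptors TNFRSF10A and TNFRSF10B changed by -2.63 and -2.16, BCL2L1 fell by 1.03 and BNIP3L rose by 1.39. The BCL2 family list gave adjusted p of 0.20 at 4 h and 0.085 at 8 h, and it passed at all 3 times without the detection filter (0.044, 0.035 and 0.045). Of 17 genes of the dasatinib target list, kinases apart from the fusion partner BCR, 4 rose and 7 fell at 24 h (adjusted p = 0.44), with a median of 0.12 and a mean of -0.22, which differ in sign. They also differed in sign at 8 h, at 0.01 and -0.11. The SRC family kinase LYN changed by -0.60, -1.18 and -1.73 at 4 h, 8 h and 24 h. BCR and ABL1, the partners of the fusion, were not called at any time, with 0.21 (SE 0.22) and 0.16 (SE 0.11) at 24 h. Of 6 megakaryocyte genes 1 rose at 24 h, TUBB1, and the list gave adjusted p of 0.24, 0.11 and 0.54 at 4 h, 8 h and 24 h. Of 19 cholesterol synthesis genes, 2 rose and 9 fell at 24 h (adjusted p = 0.065), and the reductase DHCR7 fell by 1.06. This list passed at 24 h without the detection filter (adjusted p = 0.011), with the authors' value table (0.044) and without array C of the 24 h group (0.047). At 4 h and 8 h that list gave adjusted p of 0.16 and 0.44, with a mean of -0.06 and a median just above 0 at 8 h, and it passed at 4 h without the detection filter (0.049). Of 14 interferon-stimulated genes, 9 rose and 2 fell at 24 h (10 and 2 adjusted over the list alone; median 0.65, or 0.60 with bounds; adjusted p = 0.077), including IFI6 at 1.68 and the factor IRF1 at 1.52. That list gave adjusted p of 0.50 at 4 h and 0.10 at 8 h. Of the 20 genes of the cytokine receptor list 7 rose and 7 fell at 24 h (7 and 7 adjusted over the list alone; adjusted p = 0.96), with a median of 0.01 and a mean of -0.04, and at 8 h the list gave an adjusted p of 0.24. Of the amino acid and ATF4 genes, 9 rose and 5 fell at 24 h (9 and 5 adjusted over the list alone; adjusted p = 0.71), with TRIB3 at -1.40 and the factor DDIT3 at 1.04. Of 14 reference genes 2 rose and 4 fell at 24 h (2 and 3 adjusted over the list alone; adjusted p = 0.79), with TBP at -0.51 and GAPDH at -0.43. At 4 h and 8 h the reference genes gave adjusted p of 0.67 and 0.58, and at 4 h their mean was 0.04 and their median just below 0. BCL6, fixed by name, was not measured.

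Between 4 h and 8 h of dasatinib no vehicle is involved, and the length of exposure and the time in low-serum medium differ together. The same holds for the other comparisons between times. AQP1, a water channel of red cells, was at least 3.46-fold higher at 8 h, TUBB1 rose by 1.84, FAXDC2 by 1.69, MLXIPL, a glucose-responsive factor, by 1.59 and SLC45A3 by 1.58. ETV5 was at least 3.48-fold lower, DDIT4 fell by 1.97 (SE 0.20), HJV, a coreceptor of iron regulation, fell by 1.79, the zinc transporter SLC39A10 fell by 1.69 and CCDC26 fell by 1.65. In total 1151 genes (11.3%) were called, 610 higher and 541 lower, and 110 at 2-fold. Without array B of the 8 h group 686 were called, without its array A 734, and with only these groups in the fit 718. Without background correction 15 passed at 2-fold.

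The amino acid and ATF4 list fell between these times. Of 26 genes, 14 fell and 0 rose (15 and 0 adjusted over the list alone), with a median of -0.51 (adjusted p = 3.9e-14). SESN2 fell by 1.54, STC2 fell by 1.49 and CEBPG fell by 1.41. Of the 26 genes of MYC and ribosome biogenesis, 18 fell and 0 rose (22 and 1 adjusted over the list alone), with a median of -0.59 (adjusted p = 4.1e-15). MYBBP1A fell by 1.38 and RRP9 fell by 1.15. Of the 36 erythroid genes, 20 rose and 0 fell (22 and 0 adjusted over the list alone), with a median of 0.47 (adjusted p = 8.6e-11). EPB42 was at least 2.20-fold higher and NFE2 rose by 1.06. The FOXO target and cell cycle exit list passed with 7 higher and 0 lower (8 and 1 adjusted over the list alone), including YPEL3 at 1.06. Its median was 0.13 (adjusted p = 0.0019, or 0.082 with an estimated correlation). STAT5 targets did not pass between times, and from 4 h to 24 h their median of 0.02 and mean of -0.28 differed in sign (adjusted p = 0.44). Mitosis genes passed from 4 h to 8 h with 4 higher and 0 lower (4 and 0 adjusted over the list alone; median 0.21, adjusted p = 0.0016; adjusted p = 0.21 with an estimated correlation). DNA replication genes passed with 2 lower and 0 higher (2 and 0 adjusted over the list alone; median -0.11, adjusted p = 0.024; adjusted p = 0.11 with an estimated correlation).

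Between 4 h and 24 h, CA1 rose by 5.26 and ESPN by 5.14, SLC4A1 was at least 26.4-fold higher, EPB42 at least 22.7-fold higher and ANO1 at least 15.3-fold higher. MT1X fell by 3.79 (SE 0.28), CD3D fell by 3.34, VGF fell by 3.23, SLC25A22 fell by 2.78 and HJV was at least 3.92-fold lower. In total 4668 genes (45.7%) were called, 2366 higher and 2302 lower, and 1002 at 2-fold, of which 590 were higher and 412 lower. Without background correction 367 passed at 2-fold, and the authors' value table gave 233.

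Of the 36 erythroid genes, 30 rose and 0 fell from 4 h to 24 h (31 and 0 adjusted over the list alone), with a median of 1.09 (adjusted p = 1.3e-14). Of the 26 genes of MYC and ribosome biogenesis, 24 fell and 1 rose (24 and 1 adjusted over the list alone), with a median of -1.15 (adjusted p = 8.7e-13). RRP12 fell by 2.30, RRP9 fell by 1.97 and NOLC1 fell by 1.85, and the 1 that rose was MYC itself, by 0.74 (SE 0.13). Of the 24 genes of the FOXO target and cell cycle exit list, 15 rose and 2 fell (15 and 2 adjusted over the list alone). Their median was 0.65 (0.57 with bounds, adjusted p = 5.3e-05). YPEL3 rose by 3.08 and YPEL5 by 2.21. Of the 26 amino acid and ATF4 genes, 19 fell and 1 rose (20 and 1 adjusted over the list alone), with a median of -0.52 (adjusted p = 1.2e-05; adjusted p = 0.082 with an estimated correlation). SLC7A5 fell by 1.48, TRIB3 fell by 1.44 and DDIT4 fell by 1.40, and DDIT3 rose by 0.58. Of the 21 heat shock genes and chaperones, 14 fell and 0 rose (15 and 0 adjusted over the list alone), with a median of -0.43 (adjusted p = 1.9e-05; adjusted p = 0.055 with an estimated correlation). Of the 21 glycolysis genes, 13 fell and 2 rose (13 and 2 adjusted over the list alone), with a median of -0.36 (adjusted p = 0.0063; adjusted p = 0.17 with an estimated correlation). Of the 8 fibroblast and epithelial markers, 5 fell and 0 rose (5 and 0 adjusted over the list alone), with a median of -0.67 (adjusted p = 0.035; adjusted p = 0.29 with an estimated correlation). That call was lost without array C of the 4 h group (adjusted p = 0.062) and without the detection filter (0.19).

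Between 8 h and 24 h, SLC4A1 was at least 27.5-fold higher, ESPN rose by 4.68 and CA1 by 4.27. Among noncoding RNAs, the 5S ribosomal RNA RNA5S9 rose by 3.89 (SE 0.13) and the U1 small nuclear RNA RNU1-3 by 3.78 (SE 0.16). MT1X fell by 3.43, CD3D fell by 2.65, VGF fell by 2.53, the calcium-binding protein NECAB1 fell by 2.36 (SE 0.42) and the fatty acid-binding protein FABP5 fell by 2.24. In total 3647 genes (35.7%) were called, 1784 higher and 1863 lower, and 489 at 2-fold, of which 325 were higher and 164 lower. Without background correction 147 passed at 2-fold, and the authors' value table gave 95.

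Of the 36 erythroid genes, 27 rose and 0 fell from 8 h to 24 h (27 and 0 adjusted over the list alone), with a median of 0.61 (adjusted p = 4.4e-12). EPB42 rose by 3.37 and ALAS2 by 3.05. Of the 26 genes of MYC and ribosome biogenesis, 18 fell and 0 rose (20 and 1 adjusted over the list alone), with a median of -0.54 (adjusted p = 1.3e-07). RRP12 fell by 1.51, PES1 fell by 1.11 and TBRG4 fell by 1.09. Of the 21 heat shock genes and chaperones, 16 fell and 0 rose (18 and 0 adjusted over the list alone), with a median of -0.46 (adjusted p = 3.9e-06). Of the 8 fibroblast and epithelial markers, 6 fell and 0 rose (8 and 0 adjusted over the list alone), with a median of -0.54 (adjusted p = 0.00042; adjusted p = 0.14 with an estimated correlation). Of the 24 genes of the FOXO target and cell cycle exit list, 10 rose and 2 fell (10 and 2 adjusted over the list alone). Their median was 0.34 (0.30 with bounds, adjusted p = 0.00082, or 0.065 with an estimated correlation). Of the 21 glycolysis genes, 12 fell and 3 rose (14 and 4 adjusted over the list alone), with a median of -0.52 (adjusted p = 0.0035; adjusted p = 0.15 with an estimated correlation). PKM fell by 2.16, PGAM1 fell by 1.54 and LDHA fell by 1.17.

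**Figure D4:**
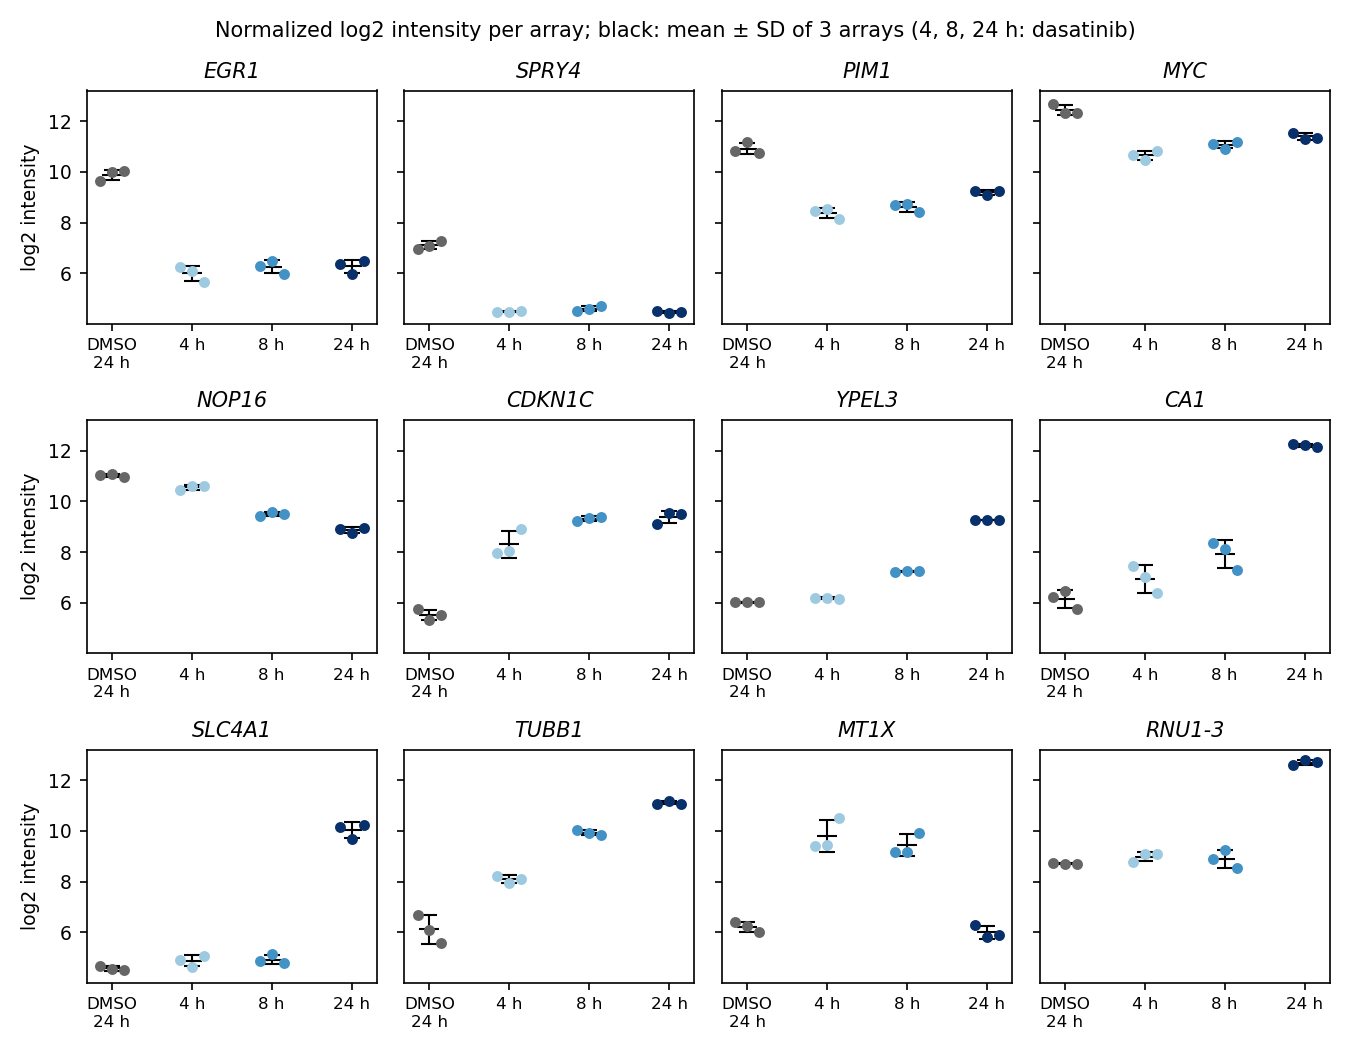
Normalized log2 intensity of 12 named genes on each array (points) with the mean and SD of each group (n = 3), in DMSO and after 4 h, 8 h and 24 h of dasatinib. EGR1 is low at all 3 times, MT1X is high at 4 h and 8 h alone, and CA1, SLC4A1 and RNU1-3 are highest at 24 h.

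The genes called at different times overlapped in direction. Of the 1219 genes called at 4 h, 1002 (82.2%) were called in the same direction at 8 h, 452 higher and 550 lower, where 89.6 and 104.5 would be expected from independent calls, and 6 were opposite. From 4 h to 24 h, 941 (77.2%) had the same direction, with 145 and 184 expected for 419 higher and 522 lower, and 48 were opposite. From 8 h to 24 h, 2611 genes (80.0% of those at 8 h) had the same direction and 50 were opposite. That last count was 29, 30 and 25 without DMSO array A, B or C, and 33 without array C of the 8 h group. The 48 became 26, 27 and 26 without DMSO array A, B or C, and 31 without array C of the 4 h group or array A of the 24 h group. The 6 became 3 without DMSO array A or array C of the 4 h group. The correlation of log2 fold changes across genes, which are not independent replicates, was 0.769, 0.557 and 0.754 for these pairs. Because the comparisons share the 3 DMSO arrays, unchanged genes also correlate, at 0.498, 0.499 and 0.497 in 50 simulations. A correlation of that size follows from the sharing whatever the noise, so it does not measure the part of the shared arrays in the observed values. The covariance, which does depend on the noise, was 0.140, 0.156 and 0.293, against 0.0129, 0.0129 and 0.0128 in the simulations. A deviation common to the DMSO arrays was not part of these simulations. The mean number of shared calls in those was 0.02, 0 and 0. No gene was changed in them, so hardly any could be called, and these counts do not measure what the shared controls add. The DMSO arrays are too few to be split, so part of the excess over independent calls can come from the shared controls.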

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

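In this part the test of time in the medium was chosen only after the result was seen. The changes at 4 h and at 24 h differed in direction for 48 genes, each called at both times against DMSO. The difference between the times was called for each as well. Opposite calls make that certain, since the difference exceeds either change at the same SE, so it adds no evidence. Of the 48 genes, 16 were higher at 4 h and lower at 24 h, and 32 the reverse. The count of opposite calls was 26, 27 and 26 without DMSO array A, B or C, 31 without array C of the 4 h group or array A of the 24 h group, and 26 with only 2 groups in the fit. At stricter thresholds it was 10 at an adjusted p under 0.01 and 4 at 2-fold at both times. SLC45A3, a solute carrier, went from -1.13 to 2.13, a difference of 3.26 (SE 0.19, adjusted p = 1.1e-07). RIPOR3 went from -1.03 to 1.69, a difference of 2.72. GDF15, a stress-induced secreted factor, went from -1.09 to 1.45, a difference of 2.53. MAPRE3, a microtubule end-binding protein, went from -1.01 to 1.07, a difference of 2.08. The erythroid factor NFE2 went from -0.86 to 0.46, and NTS, the precursor of neurotensin, from 0.87 to -1.53.

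MT1X was 3.58 above DMSO at 4 h, still 3.22 above it at 8 h and at -0.20 at 24 h (adjusted p = 0.57). The difference between 4 h and 24 h was -3.79. A rise at 4 h that was lost sooner was seen in the amino acid and ATF4 list, with a median of 0.59 at 4 h and 0.04 at 8 h. Leaving out any 1 array left the list's median at 0.48 or more and MT1X at 3.23 or more, which argues against a single array as the source. Of the 1219 genes called at 4 h, 160 (13.1%) were not called at 24 h and had moved back toward DMSO, 73 from above and 87 from below. Time in the medium rather than the drug may give such a course, and the 2 cannot be told apart here because the vehicle arrays are from 24 h alone. A transient response to dasatinib remains an open explanation, untested for the same reason.

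Probes that name no single gene were outside the comparisons of genes. Of 4228 such probes that passed the detection filter, 1607 were called at 24 h against DMSO, 810 higher and 797 lower, with 368 at 2-fold. What these probes measure was not analysed here.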

How the results depend on the processing

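No called result of a named gene changed direction under the alternatives run for genes, and no called list did under those run for lists, which left out offset 50, median scaling, the mean of all probes, the stricter filter, only 2 groups in the fit, the other prior and array weights. Of 533 results for named genes, 484 were called, and the calls lost numbered 4 with offset 50, 5 each with a trended robust prior and with array weights, 6 each with the mean of all probes and with a replicate block, 9 under cyclic loess, 10 without background correction, 18 under median scaling, 19 without the detection filter, and 24 each with the authors' value table and with only the 2 groups compared. With 1 array left out, 52 of them lost the call at least once. Values that were not called changed sign 11 times under median scaling, 5 under cyclic loess, 4 each with the mean of all probes and with array weights, 1 time with the authors' value table and 27 times over the fits with 1 array left out. Of 48 calls of lists, 1 was lost under cyclic loess, 2 without the detection filter, 3 with 1 array left out and 23 with an estimated correlation. Lists also gained a call, 12 times without the detection filter, 3 with the authors' value table, 2 each without background correction and with a replicate block, and 8 over the fits with 1 array left out. The balance of higher and lower calls moved with the scaling. For 24 h against 8 h it was 1446 to 2226 under median scaling and 1932 to 1632 under cyclic loess, for 24 h against 4 h 1988 to 2682 and 2535 to 2097, and for 24 h against DMSO 2445 to 3077 and 2884 to 2723. The cause was not tested. Calls of dim genes are limited by their signal over background. The slide block was not run because the files name no slides.

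Counts at 2-fold are given in the order 4 h, 8 h and 24 h against DMSO, 8 h against 4 h, 24 h against 4 h and 24 h against 8 h. Without background correction they were 39, 129, 613, 15, 367 and 147, and 22, 63, 381, 9, 233 and 95 with the values of the authors' table. Background left in the signal narrows fold changes, as does a larger offset; for the authors' table the cause was not tested. With offset 50 they were 114, 295, 48, 656 and 281 for the comparisons other than 24 h against DMSO. With detection on all 12 arrays at p under 0.01, which tests fewer genes, they were 102 (4 h), 323 (8 h), 60 (8 h against 4 h) and 295 (24 h against 8 h). The minimum-fold test of 1.5 gave 109 (4 h) and 30 (8 h against 4 h). Counting every probe gave 8420 called and 2268 at 2-fold at 24 h, 1549 at 2-fold for 24 h against 4 h and 808 for 24 h against 8 h. With only the 2 groups in the fit, and so fewer residual degrees of freedom, 8 h against 4 h gave 718. Leaving out 1 array gave 808 (without DMSO array C) to 1168 genes called at 4 h and 686 (without array B of the 8 h group) to 1130 for 8 h against 4 h.

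Shared calls in the same direction for 4 h and 8 h, 4 h and 24 h, and 8 h and 24 h were 482, 459 and 1563 at an adjusted p under 0.01, and 159, 149 and 421 at 2-fold, as these thresholds are stricter. Opposite calls, 6, 48 and 50 for these pairs, were 1, 10 and 12 at an adjusted p under 0.01 and 0, 4 and 1 at 2-fold. In the order of the comparisons above, the number of lists passing was 10, 9, 10, 6, 7 and 6 of 21. It was 5, 5, 6, 3, 3 and 3 with an estimated correlation and 15, 16, 19, 14, 19 and 14 with fry, which does not compare a list with other genes.

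The letters of the arrays do not state a pairing. Residuals of same-letter arrays had correlations of -0.085 to 0.193 across genes (mean 0.058, with 4 of 18 pairs over 0.1). Over 36 pairs of different letters the mean was -0.029. Residuals cancel within a group, so this mean is tied to that of the same letter and is not separate evidence. For 10 of 12 arrays the mean correlation with arrays of other groups was highest for their own letter. With the letter as a block, 1245, 3347, 5606, 1229, 4782 and 3747 genes were called in the 6 comparisons.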

Other observations

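In this part the gene families were chosen after the data were seen, as were the tests of the small nuclear RNAs, while the tests of other splits and of the globin signals were set before their results. At 24 h probes for small nuclear RNAs, most of them RNA parts of the spliceosome, gave higher signals. Of 13 measured genes in this class, taken by symbol, 12 rose and 0 fell, with a median of 2.40, where at 4 h and 8 h 1 had risen. RNU4-2 rose by 3.62 (SE 0.24), RNVU1-18, a U1 variant, by 3.73 (SE 0.13) and RNU6-1 by 0.86 (SE 0.10). The member that was not called, RNU105C, is annotated as a small nucleolar RNA (-0.24, SE 0.28, adjusted p = 0.50). The U1 probes may read near-identical copies, a point left open as probe sequences were not aligned, but RNU2-1 of the U2 class rose too, by 2.11, and under each of 5 other normalizations 12 of the class were called higher. RN7SK, a regulator of transcription elongation, rose by 3.61 (SE 0.13), RMRP by 1.75 and RPPH1 by 1.34, whereas RN7SL1 gave 0.02 (SE 0.10). All 3 U3 RNAs, which guide early ribosomal RNA cleavage, rose at 24 h (median 2.97), and of 109 other small nucleolar RNAs 18 rose and 25 fell. Of 13 small Cajal body RNAs 7 rose and 1 fell under each normalization run, with a median of 0.86 that was 0.27 without background correction, 0.48 with offset 50 and 0.12 with the authors' value table.

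Replication-dependent histones, whose messages lack a poly(A) tail in dividing cells, also gave higher signals at 24 h. Of 44 measured, 36 rose and 2 fell, with a median of 0.74, and 32 to 36 rose under every normalization run, although the median was 0.44 without background correction and 0.33 with the authors' value table. H4C2 rose by 2.63 and H4C1 by 2.02, and H2BC11 and H4C8 were the 2 that fell. Of 7 metallothioneins measured, 3 rose at 4 h (median 0.46) and 3 at 8 h (median 0.27). At 24 h 4 fell and 0 rose (median -0.45), although 1 rose with offset 50, cyclic loess or median scaling.

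The scaling of the arrays is a candidate explanation of the higher small nuclear RNAs. A first bound, set before its result, on the class median (under 0.5 for it, above 1 under every normalization against it) was met by neither side, since the authors' value table gave 0.93. A count chosen after that result gave 12 of 13 called higher under each of 5 other normalizations. The calls thus held under each scaling run, but a count chosen so late cannot decide, and scaling stays open as part of the source. A lower share of poly(A) messenger RNA would raise other RNAs alike. Yet 69 small nucleolar, Y and vault RNAs detected on all 12 arrays had a median of -0.17 (quartiles -0.47 and 0.08). For 9 small nuclear RNAs detected on all 12 arrays it was 3.34 (2.03 and 3.73). Without that filter the 13 small nuclear RNAs had a median of 2.40 (0.98 and 3.62), and the 109 other small nucleolar RNAs -0.14. The 6 Y and vault RNAs had 0.35, with 2 higher and 1 lower. The U3 RNAs, RN7SK, RMRP, RPPH1, 7 of 13 small Cajal body RNAs and most of the histones did rise, while RN7SL1 did not. The rise was therefore not shared by all such RNAs, but a lower share of messenger RNA stays open as part of the source. The mean of the small nuclear RNAs was 9.68 to 9.76 on the 3 arrays at 24 h and 7.25 to 7.63 on the other 9. The labels name no batch, and a response to dasatinib stays open, untested. How the labelling reads RNAs without a poly(A) tail was not examined, so higher signals need not be higher amounts.

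The abundant globins did not follow the other erythroid genes. HBG1, HBG2 and HBA2 gave 0.02, 0.02 and -0.08 at 24 h and were not called, with DMSO signals of 21392, 22473 and 21990, while HBE1 rose by 2.18 (SE 0.10), HBD by 1.97, HBB by 1.45 and HBA1 by 0.57, and HBZ rose as well (adjusted p = 8.2e-05). Signals at the top of the measured range may hide a rise. Of the 50 genes brightest in DMSO 0 rose by over 0.5 and 1 fell by that much, which meets neither bound set for this test. The highest signal of any probe was 31796. Genes this bright had little room below that signal for a rise of over 0.5, so the test could hardly decide. Compression of bright signals and level expression cannot be told apart from these values.

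Of 100 splits of the 12 arrays into 4 groups of 3, the real one alone, 1 of 100, called as many as 5919 genes in the F test. That share, under 0.05, argues against a random grouping of the arrays as the source of the count. It cannot speak to a culture or run shared by the arrays of a group. The highest other split called 3241 and kept together 5 of the 12 pairs of arrays of a real group, where the median of the others was 2. For each of the 6 comparisons 10 splits are too few for a share under 0.05. The real split alone, 1 of 10, gave the 1219, 3265, 5511, 1151, 4668 and 3647 genes of the report, and the highest other gave 0, except 1 for 8 h against 4 h.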
